A study of Homo sapiens with 3 samples.

How the data were processed

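RNA was sequenced from SU-DHL-4 cells, a human cell line of diffuse large B-cell lymphoma, in 3 libraries, 1 for each of the treatments A740003, BzATP and PBS. Per the labels' protocols, the cells were grown in RPMI-1640 medium with fetal bovine serum and treated for 48 h, A740003 and BzATP were used at 50 µM, and libraries were made from total RNA by Illumina protocols. The labels name PBS as the only control, and the solvent of A740003 is not given in the sources used here, so a ratio of A740003 to PBS can include an effect of the solvent. The aligner, the counting tool, the genome build, the strand setting and the use of poly(A) selection are not given in the sources used here.

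Both tables used here list the same 60664 genes by Ensembl ID and symbol. The first holds the authors' estimated counts per gene, from sequencing reads and with no normalization between libraries stated in the file headers. About 22% of the values above 0 in each library are not whole (21.8% for A740003, 22.3% for BzATP and 22.2% for PBS), as when reads that fit several genes are divided between them. The second holds the authors' deposited FPKM values, fragments or reads scaled by gene length and library size, with a denominator that is not given in the sources used here. Column names A, B and C were matched to the sample titles that open with the same letters.

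The estimated counts were rounded to whole numbers. Library totals were 18029275 for A740003, 18042301 for BzATP and 18270848 for PBS. Genes listed by ID without a symbol, which were kept, held 0.610%, 0.592% and 0.549% of these. Counts were scaled to CPM, a rate per library size, with TMM factors from edgeR 4.0.16 in R 4.3.3, which were 1.02 for A740003, 1.02 for BzATP and 0.965 for PBS. Later steps, apart from other scaling factors computed in R, used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6. Genes with a mean CPM of at least 1 over the 3 libraries were tested, which left 11524 genes, 10249 of them protein coding. Gene types, GC content and transcript lengths came from GENCODE 29, in which 58396 of the listed genes were found by Ensembl ID. No coordinates are printed, since the files name no build.

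With 1 library per treatment there is no spread between replicates, so edgeR's quasi-likelihood test could not be fitted and no p-value was computed. A gene was called by a rule of size instead: a ratio of at least 2-fold between the CPM of the libraries, with an exact 95% counting interval (Clopper-Pearson, conditional on the gene's summed count) that excluded no difference. Nothing was added to the counts. A count of 0 allows up to 3 counts, which is 0.163 CPM for A740003, 0.164 CPM for BzATP and 0.170 CPM for PBS. Reads carry no molecular identifiers in the sources used here, so all intervals and floors cover counting error only and describe these libraries, not the treatments.

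Before the data were examined, 41 gene lists were fixed, covering pathways, complexes, B-cell programmes, library-quality markers and markers of other cell types. All 1042 listed symbols were matched, and 36 lists had at least 5 tested members. The median log2 ratio of each list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and a list stood apart outside the middle 95% of them. By chance 1.8 of 36 lists would do so if genes varied independently. Genes of a pathway vary together between any cultures, which random lists do not measure. In the text, list members are counted as higher or lower by whether their own counting interval excludes no difference. The rule fixed in advance also asked for a ratio of at least 1.5-fold. By that rule, 0 members of the ribosome biogenesis, glycolysis, heat shock and DNA replication lists were lower with A740003 than with PBS. For ATF4 targets it was 2 of 28, and for G2/M genes with BzATP against PBS 0 of 28. For lists with higher medians against PBS, 0 of 24 cholesterol synthesis genes were higher by it with A740003 and 2 of 24 with BzATP. For B-cell receptor signalling it was 0 of 25 with either compound. With BzATP it was 2 of 31 for autophagy and lysosome and 0 of 16 for MHC class II. Against BzATP, A740003 had 0 of 28 G2/M genes higher and 1 of 16 MHC class II genes lower. Abundant noncoding RNAs had 6 of 11 higher with A740003 against PBS.

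The genes named in the text were chosen by a rule fixed together with the lists. Per comparison these are the 12 highest and 12 lowest genes by the bound of the counting interval nearest to no difference, at a mean CPM of at least 5 and without clone-based names or pseudogenes, and the 4 leading members of each list that stood apart. P2RX7, P2RX4 and the other purinergic receptors with a mean CPM of at least 1 were added. A few genes that the rule selects are not reported here. Genes named outside this rule, among them list members given only as having 0 reads, were chosen after their values were seen. Where a named gene has a near-identical copy or an overlapping readthrough gene, counts were summed over them. The families to sum were chosen after the values were seen.

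The ratios of both compounds to the shared PBS library were set beside 50 simulations of unchanged libraries at each of 3 assumed biological coefficients of variation (0, 0.1 and 0.2). The lists that stood apart in both comparisons were counted in such simulations too, a step added after the data had been seen. The rules were tested on simulated counts drawn from the real means and library sizes, with 200 changed genes. These counts held counting error only, with no variation between cultures. The changed genes were drawn from above the lowest tested levels. In the simulated A740003 and PBS comparison over 11531 genes, 50 of 50 genes changed 3-fold and 30 of 50 changed 2-fold were called, with 16 unchanged genes called. For BzATP and PBS over 11536 genes these were 50 of 50, 32 of 50 and 16, and for A740003 and BzATP over 11531 genes 50 of 50, 23 of 50 and 15. None of 50 genes changed 1.5-fold was called in any of the 3 comparisons.

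Alternatives fixed in advance were scaling by total counts, by DESeq2 1.42.0 size factors or by upper quartile, no filter or a mean CPM of at least 5, FPKM with a pseudocount of 0.1 or 1, thinning to the shallowest library, thresholds of 1.5-fold and 3-fold, protein-coding genes only, list means, and a random split of the PBS reads into 2 equal parts. Removal of a lowess trend of the log2 ratio with GC content and then with transcript length (span 0.3), and scaling without the A740003 library, were added after the data had been seen.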

Results

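SU-DHL-4 is an established human line of diffuse large B-cell lymphoma. Cells were treated for 48 h with 50 µM A740003, an antagonist of the ATP-gated P2X7 receptor, with 50 µM BzATP, an agonist of that receptor, or with PBS, and RNA was sequenced from 1 library per treatment. The design text names BzATP and A740003 as agonist and antagonist of P2X7 and PBS as the control; P2X7 signalling itself was not measured here, and the solvent of A740003 is not given in the sources used here. The libraries held 18029275 (A740003), 18042301 (BzATP) and 18270848 (PBS) estimated reads on genes, and 18109, 18032 and 17590 genes had at least 1 read. Mitochondrial genes took 5.56%, 6.11% and 5.75% of the reads. Ratios are log2 ratios of TMM-scaled CPM with 95% counting intervals in brackets. List members are counted as higher or lower by that interval alone, and in most lists few or none reached 1.5-fold. With no replicates, no difference has a replicate check, and every interval describes these 3 libraries only.

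P2RX7 (ENSG00000089041), which encodes the receptor that both compounds are named for, was at or under the detection floor in all 3 libraries. It had 0 estimated reads with A740003, 0 with BzATP and 1 with PBS. By the floor of 3 counts, a count of 0 allows up to 0.163 CPM with A740003 and 0.164 CPM with BzATP, so no ratio of P2RX7 is given. Several other purinergic receptors were well covered. P2RX5 had 1868, 2163 and 1656 reads with A740003, BzATP and PBS, which is 0.33 [0.24 to 0.42] higher with BzATP and 0.11 [0.02 to 0.21] higher with A740003 than with PBS. P2RY8 had 2959, 2833 and 2960 reads and ADORA2A, an adenosine receptor, 1461, 1608 and 1400. P2RY11 was lower with A740003 (-0.40 [-0.65 to -0.15]) and with BzATP (-0.31 [-0.56 to -0.07]) than with PBS. P2RX4 had 42, 55 and 60 reads, and its ratio of A740003 to PBS (-0.58 [-1.18 to 0.02]) was within counting error. The list of purinergic receptors and ATP-handling enzymes had 7 measured members. It did not stand apart from random lists in any of the 3 comparisons (medians of -0.02, -0.12 and -0.09). With a trend of GC content and length removed, the median changed sign with A740003 against PBS (0.08, percentile 79.8) and against BzATP (0.16, percentile 95.7). Both still lay within random lists. Of the inflammasome genes, NLRP3, CASP1, IL1B and IL18 had 0 reads in each library, and the list's 6 measured members did not stand apart with A740003 (percentile 85.3) or BzATP (percentile 87.8) against PBS.

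The comparison of A740003 with PBS asks what differed when the receptor antagonist was present. In the A740003 library the mitochondrial ribosomal RNAs and the RNA of the signal recognition particle were higher, while most mitochondrial mRNAs were lower. MT-RNR1, the small mitochondrial ribosomal RNA, was 2.58-fold higher (1.37 [1.34 to 1.39]), MT-RNR2 was 0.72 [0.71 to 0.73] higher, and RN7SL1 and RN7SL2, near-identical copies, were 1.45 [1.29 to 1.60] higher when summed. Of 13 mitochondrially encoded mRNAs, 12 were lower, with a list median of -0.46, led by MT-ND5 (-0.66 [-0.68 to -0.64]), MT-ND4 (-0.63 [-0.64 to -0.62]), MT-ATP6 and MT-CO3. The exception was MT-ND6, encoded on the other strand, at 1.19 [1.13 to 1.24]; without a stated strand setting its reads cannot be separated from antisense reads. All 11 measured abundant noncoding RNAs lay above PBS, with a list median of 0.60.

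**Figure D1:**
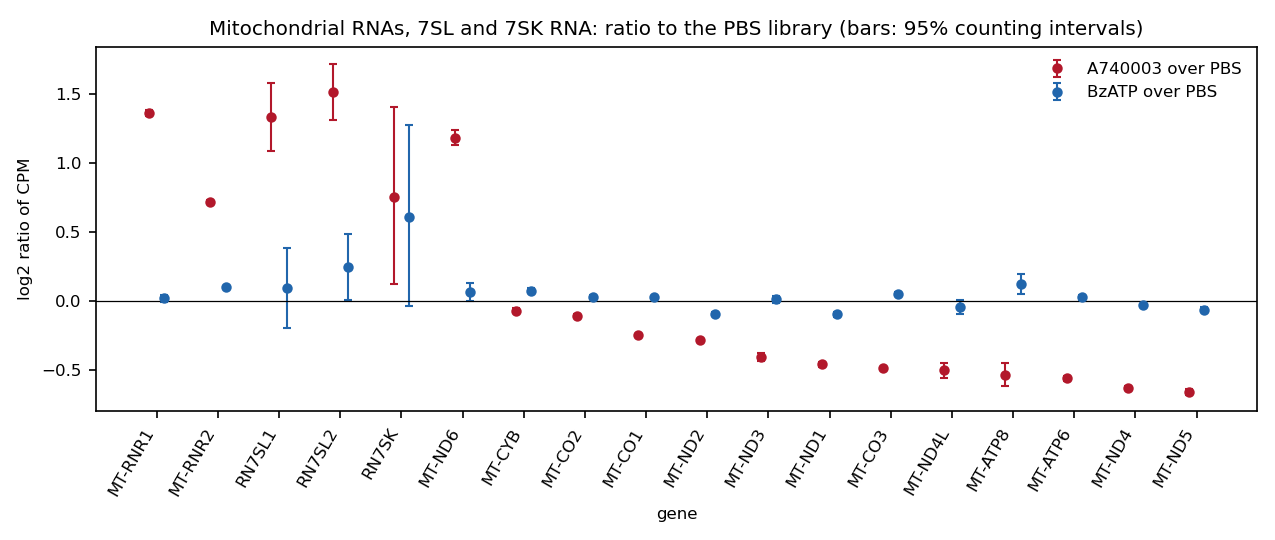
Log2 ratio to the PBS library (vertical axis) of mitochondrial RNAs, RN7SL1, RN7SL2 and RN7SK (horizontal axis) in the A740003 library (red) and the BzATP library (blue), with 95% counting intervals as bars. With A740003, MT-RNR1 lies at 1.37 and MT-ND5 at -0.66, while with BzATP the same genes lie at 0.02 and -0.06.

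Ribosome biogenesis, glycolysis, heat shock, amino acid response, DNA replication and nucleotide synthesis genes were mostly lower in the A740003 library than in the PBS library. The ratio of A740003 to PBS was also lower at higher mean CPM (Spearman -0.13 across 7034 genes). Counts of lower members were not compared with those of equally abundant genes. Ribosome biogenesis and MYC target genes had a list median of -0.29, with 24 of 27 members lower and 0 higher, among them PES1 (-0.55 [-0.62 to -0.48]), MYBBP1A (-0.55 [-0.64 to -0.46]), RRP9 and PA2G4. Glycolytic genes had a median of -0.27, with 18 of 20 lower, led by ENO1 (-0.52 [-0.55 to -0.50]) and ALDOA (-0.51 [-0.54 to -0.47]), then GPI and PKM. Heat shock genes had a median of -0.23, with 16 of 20 lower and 1 higher, such as the co-chaperones FKBP4 (-0.54 [-0.58 to -0.51]) and STIP1, and HSP90AB1 and HSPD1. ATF4 targets of the amino acid response had a median of -0.20, with 19 of 28 lower and 3 higher, including VLDLR (-0.76 [-0.95 to -0.57]), SHMT2, AARS1 and the amino acid transporter SLC7A5. DNA replication genes had a median of -0.19, with 23 of 28 lower and 2 higher, such as the helicase subunits MCM7 (-0.49 [-0.52 to -0.45]), MCM2 and MCM5, and CDC45. Nucleotide synthesis genes had a median of -0.17, with 17 of 24 lower and 3 higher, among them CAD (-0.46 [-0.55 to -0.37]), NME1, PFAS and PAICS.

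Lists of sterol synthesis, NF-kB target, FOXO target, B-cell receptor signalling, cytokine and hypoxia genes had higher medians in the A740003 library than in the PBS library, with members on both sides. Cholesterol synthesis genes had a median of 0.14, with 14 of 24 higher and 4 lower, led by INSIG1 (0.57 [0.52 to 0.62]), MSMO1 (0.57 [0.47 to 0.67]), HMGCS1 and IDI1. NF-kB targets had a median of 0.15, with 7 of 18 higher and 3 lower, such as BIRC3 (0.66 [0.56 to 0.76]), CD83, BCL2A1 and the inhibitor NFKBIA; at a mean CPM of at least 5 this list no longer stood apart (median 0.09). FOXO targets had a median of 0.19, with 8 of 14 higher and 1 lower, including KLHL24 (0.58 [0.44 to 0.73]), SESN3, PIK3IP1 and CCNG2. B-cell receptor signalling genes had a median of 0.12, with 10 of 25 higher and 7 lower, among them DAPP1, CD72, the kinase SYK (0.37 [0.32 to 0.43]) and CD79B; in the FPKM values this list no longer stood apart (median 0.08 with a pseudocount of 0.1). Cytokines and their receptors had a median of 0.25, with 5 of 12 higher and 3 lower, including LTB (0.70 [0.46 to 0.94]), IL10RA, TNFRSF13C and CXCR5. Hypoxia-inducible genes had a median of 0.14, with 6 of 17 higher and 3 lower, such as BNIP3L and INSIG2, NDRG1 and P4HA1.

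By the rule of size, 127 genes were at least 2-fold higher and 64 at least 2-fold lower in the A740003 library than in the PBS library, of which 58 and 47 were protein coding. With scaling by total counts, 177 genes of any type were higher and 47 lower. The genes named next are ranked by the interval bound at a mean CPM of at least 5, and some are under 2-fold. The highest single genes included DHRS2, a short-chain dehydrogenase (2.81-fold, 1.49 [1.18 to 1.81]), LMO2, a transcriptional regulator of germinal centre B cells (1.45 [0.99 to 1.93]), the kinase WNK2 (1.23 [0.73 to 1.76]), the noncoding RNA SNHG19 (1.02 [0.76 to 1.28]) and BTG2, an antiproliferative gene with 8706 reads against 4737 (0.82 [0.77 to 0.87]). MTRNR2L1, at 0.97 [0.82 to 1.12], resembles MT-RNR2 closely enough to share its reads. The lowest included NGFR, the nerve growth factor receptor (-1.14 [-1.34 to -0.93]), NDUFAF8, an assembly factor of respiratory complex I (-1.04 [-1.23 to -0.86]), the chromatin remodeller SRCAP, with 250 reads against 478, C8orf82, FHOD3 (-0.99 [-1.24 to -0.74]), TNKS1BP1, ASMTL and ASZ1 (-0.80 [-0.92 to -0.69]). DCN, the connective tissue proteoglycan decorin, was also lower, with 742 reads against 1297 (-0.87), while the fibroblast collagens COL1A1, COL1A2 and COL3A1 had 0 reads in each library. After removal of the GC and length trend, NGFR, NDUFAF8 and C8orf82 lay at -0.97, -0.91 and -0.94, under 2-fold. ASZ1 and DCN moved farther out, to -0.98 and -0.96. Others are uncertain because a copy or readthrough gene shares their sequence. U2AF1 was at -0.97 but at -0.26 [-0.32 to -0.21] summed with U2AF1L5, SMIM11B at 1.12 but 0.21 [0.00 to 0.42] with SMIM11A, and FAM156B at -1.28 but -0.22 [-0.37 to -0.06] with FAM156A. The readthrough genes SENP3-EIF4A1 (-1.37) and P2RX5-TAX1BP3 (1.38) lay at -0.28 [-0.36 to -0.20] summed with SENP3 and at 0.17 [0.08 to 0.26] summed with P2RX5.

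Simulated unchanged libraries gave 18.1 calls on average from counting error alone. They gave 34.1 (highest 47) at an assumed biological coefficient of variation of 0.1 and 317 at 0.2, against 191 observed. At a mean CPM of at least 20, the covariance of both ratios to PBS was 0.0242. Its simulated means were 0.0230 at 0.1 and 0.0877 at 0.2, so for well-covered genes it lay near that at 0.1. This covariance reflects the PBS library and anything common to both compounds. It does not measure how the A740003 or BzATP cultures varied. Most calls were of genes with fewer reads, whose variation between cultures no replicate measures. Variation between cultures therefore stays possible for the 191 calls. At a mean CPM of at least 5, 18 genes were called higher and 8 lower. The log2 ratio was lower at higher GC content (Spearman -0.56 across 7034 genes, which are not independent replicates), with decile medians from 0.12 to -0.23; after removal of that trend 13 of the 14 lists still stood apart, the hypoxia list did not (median 0.08, percentile 96.4), and 6 others came to stand apart above their random lists: immediate early genes (percentile 99.5), apoptosis (99.7), ER chaperones (98.6), ribosomal proteins (98.9), germinal centre genes (99.9) and plasma cell genes (99.3).

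**Figure D2:**
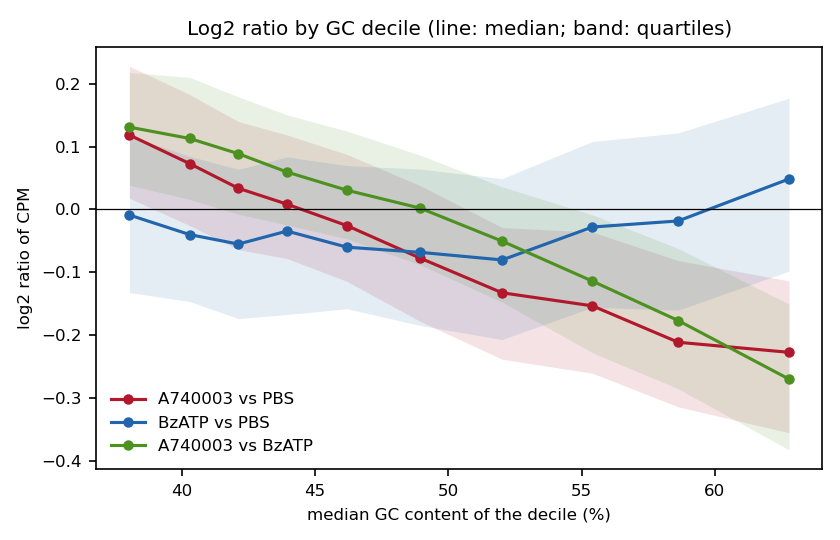
Median log2 ratio (lines, with quartiles as bands) of genes with a mean CPM of at least 20 against the median GC content (%) of each GC decile, for the 3 comparisons. The ratio of A740003 to PBS goes from 0.12 at 38.0% GC to -0.23 at 62.8% GC, while that of BzATP to PBS stays between -0.08 and 0.05.

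The comparison of BzATP with PBS asks what differed when the receptor agonist was present. The lists of NF-kB targets and sterol synthesis genes had higher medians in the BzATP library, and the list of ATF4 targets, with the transcription factors ATF5, CEBPB and ATF4 as its lowest members, had a lower one. NF-kB targets had a list median of 0.34, with 9 of 18 members higher and 1 lower, led by the survival gene BCL2A1 (0.81 [0.56 to 1.07]), CD83 (0.63 [0.52 to 0.73]), CD40 (0.57 [0.43 to 0.72]) and RELB. BCL3, a regulator of NF-kB, was 2.23-fold higher (1.16 [0.79 to 1.53]). Cholesterol synthesis genes had a median of 0.31, with 18 of 24 higher and 0 lower, such as TM7SF2 (0.66 [0.55 to 0.78]), INSIG1 (0.58 [0.53 to 0.63]) and IDI1. ATF5 was 2.10-fold lower (-1.07 [-1.16 to -0.98]), CEBPB 2.34-fold lower (-1.23 [-1.68 to -0.79]) and ATF4 1.73-fold lower (-0.79 [-0.85 to -0.73]), and ATF4 targets, a list that holds these 3 genes and VLDLR, had a median of -0.27 with 18 of 28 lower and 4 higher.

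G2/M, ribosome biogenesis, heat shock and glycolysis genes were mostly lower in the BzATP library than in the PBS library. The ratio of BzATP to PBS was lower at higher mean CPM (Spearman -0.27 across 7034 genes). Counts of lower members were not compared with those of equally abundant genes. Random lists matched on mean expression mostly had medians of -0.146 to 0.009 for G2/M and -0.161 to -0.002 for ribosome biogenesis. For heat shock these were -0.183 to 0.002, and for glycolysis -0.189 to -0.012, close to its list median of -0.203. G2/M genes had a median of -0.31, with 25 of 28 lower and 0 higher, among them CENPF (-0.53 [-0.61 to -0.45]), the cyclin CCNB1 (-0.50 [-0.57 to -0.43]), BUB1B and the kinase PLK1. Ribosome biogenesis and MYC target genes had a median of -0.39, with 25 of 27 lower, such as NCL (-0.53 [-0.55 to -0.51]), PES1, WDR43 and NOP56. Heat shock genes had a median of -0.27, with 14 of 20 lower, including HSP90AB1 (-0.52 [-0.54 to -0.50]), HSPA8, HSPD1 and FKBP4. Glycolytic genes had a median of -0.20, with 17 of 20 lower and 2 higher, such as LDHA (-0.45 [-0.47 to -0.43]), ENO1, GAPDH and PFKP. Ribosomal protein genes had a median of -0.08, with 56 of 77 lower and 7 higher, including RPS14 and RPL23A; the list median lay above random lists of equally abundant genes (percentile 99.3) and turned to 0.00011 under scaling by total counts.

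Lists of lysosomal, FOXO target, MHC and B-cell receptor signalling genes had higher medians in the BzATP library than in the PBS library. Autophagy and lysosome genes had a median of 0.20, with 19 of 31 higher and 3 lower, including the autophagy kinase ULK1 (0.84 [0.47 to 1.21]), the lysosomal enzyme GAA (0.73 [0.42 to 1.05]), PSAP and CTSS. FOXO targets had a median of 0.21, with 9 of 14 higher and 1 lower, among them TXNIP (0.60 [0.48 to 0.72]), SESN3, PIK3IP1 and the cell cycle inhibitor CDKN1B (0.65 [0.32 to 0.99]). MHC class II genes had a median of 0.12, with 10 of 16 higher and 2 lower, led by HLA-DMB (0.46 [0.38 to 0.54]), HLA-DQB1, HLA-DRB5 and HLA-DRB1, close relatives that can share reads. MHC class I genes had a median of 0.10, with 7 of 15 higher and 1 lower, including TAPBP (0.64 [0.57 to 0.72]), B2M, PSMB9 and ERAP2. B-cell receptor signalling genes had a median of 0.08, with 11 of 25 higher and 1 lower, such as CD72 (0.58 [0.44 to 0.73]), SYK, DAPP1 and the inhibitory receptor FCGR2B. Apoptosis regulators had a median of 0.09, with 13 of 27 higher and 2 lower, among them BCL2A1, BIRC3, CASP9 and BIRC2. Cytokines and receptors had a median of 0.23, with 5 of 12 higher and 2 lower, led by the receptor IL10RA, with 128 reads against 36 (1.77 [1.23 to 2.35]), CXCR5, TNFRSF13C and TGFBR2. Fatty acid synthesis genes had a median of 0.08, with 9 of 18 higher and 2 lower, including SREBF1 (0.45 [0.32 to 0.58]), ACSL3, FADS1 and ACSL5. Abundant noncoding RNAs had a median of 0.10, with 5 of 11 higher and 2 lower and NEAT1 (0.60 [0.52 to 0.68]), MALAT1, KCNQ1OT1 and MT-RNR2 ahead. ER chaperones (median 0.03, with DNAJB9, PDIA4, SYVN1 and HSP90B1 ahead) and mitochondrial mRNAs (median 0.03, with MT-CYB, MT-ATP8, MT-CO3 and MT-CO1 ahead) stood apart only relative to the lower medians of equally abundant genes.

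By the rule of size, 130 genes were at least 2-fold higher and 56 at least 2-fold lower in the BzATP library than in the PBS library, of which 87 and 36 were protein coding. With scaling by total counts, 175 genes of any type were higher and 48 lower. The genes named next are again ranked by the interval bound, and some are under 2-fold. The highest included LMO2, with 178 reads against 54 (3.17-fold, 1.66 [1.22 to 2.13]), WNK2 (1.45 [0.96 to 1.97]), the lipid transporter ABCA7 (1.10 [0.86 to 1.33]), the sulfotransferase CHST2 (1.08 [0.85 to 1.32]), TLCD1 (1.26 [0.81 to 1.71]), LAMP3 (1.00 [0.78 to 1.22]), TSPAN31 and the mitochondrial kinase PINK1 (1.04 [0.73 to 1.35]). P2RX5-TAX1BP3 (1.29), SMIM11B (1.05) and NPIPA9 (0.92), a member of a family of near-identical genes, are uncertain. The lowest included the noncoding RNA LINC00641 (-1.08 [-1.28 to -0.88]), ASZ1 (-0.89 [-1.01 to -0.77]), ZBTB12 (-1.10 [-1.44 to -0.76]), CFAP20DC, DDN (-0.80 [-0.91 to -0.69]) and DST, a cytoskeletal linker (-0.93 [-1.17 to -0.68]). FAM72D was at -0.95, and its family of 4 copies at -0.58 [-0.65 to -0.50] when summed. UTP14C was at -1.30 [-1.62 to -0.98], and its parent gene UTP14A at -0.29 [-0.40 to -0.19]. The readthrough gene FMC1-LUC7L2 (-0.96) lay at -0.36 [-0.43 to -0.29] summed with LUC7L2.

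Simulated unchanged libraries gave 36.5 and 315 calls on average at assumed coefficients of variation of 0.1 and 0.2, against 186 observed, and at a mean CPM of at least 5, 14 genes were called higher and 6 lower. The ratio had little relation to GC content (Spearman 0.04), yet with the trend removed the lists of MHC class I, cytokines, fatty acid synthesis, glycolysis and abundant noncoding RNAs no longer stood apart (percentiles 96.7, 97.2, 92.8, 2.96 and 97.3), nor did apoptosis and ribosomal proteins with no filter or mitochondrial mRNAs in the FPKM values; germinal centre genes (97.9) and interferon-stimulated genes (98.4) came to stand apart above their random lists with the trend removed.

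**Figure D3:**
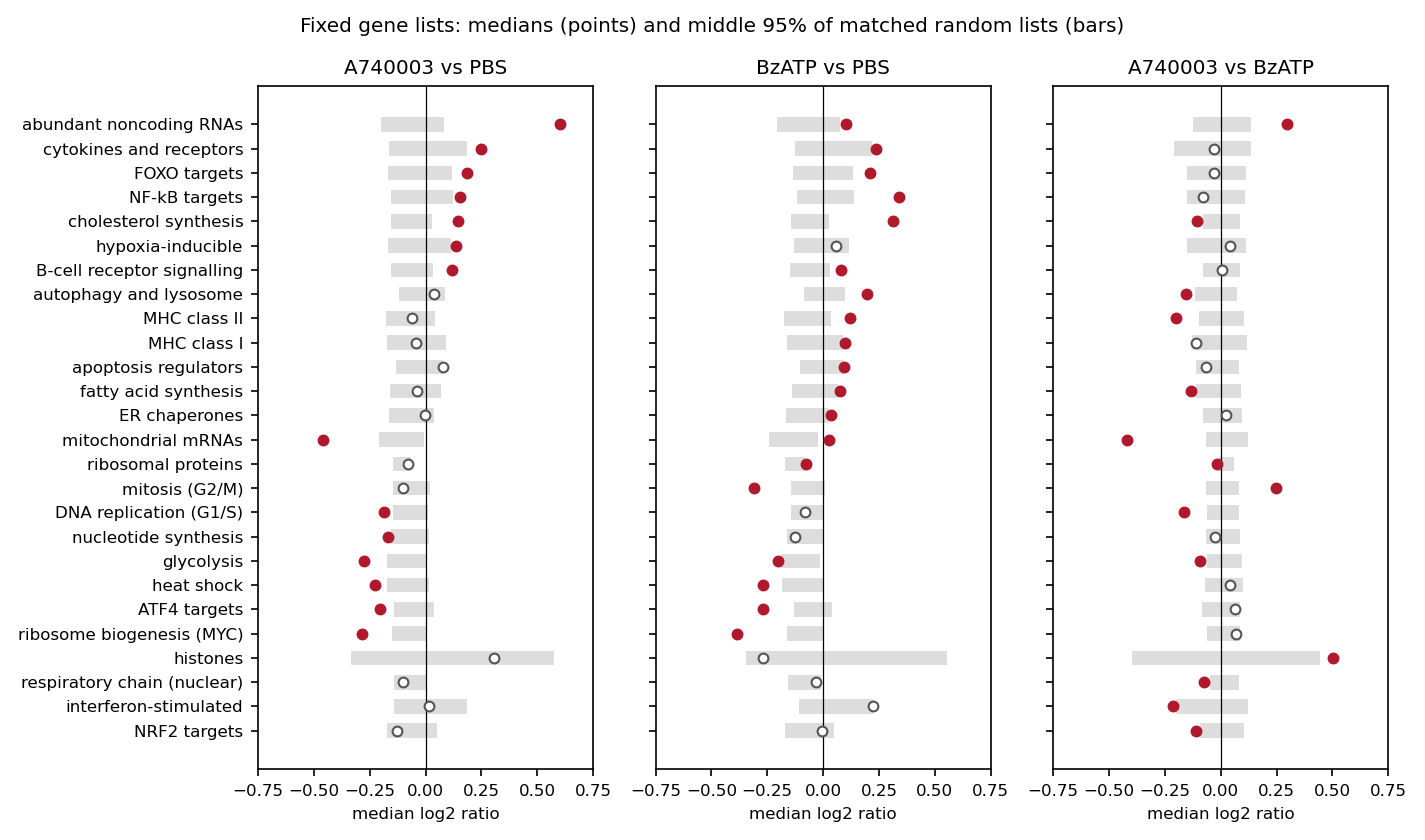
Median log2 ratio (horizontal axis) of each gene list that stood apart in at least 1 comparison, for A740003 against PBS, BzATP against PBS and A740003 against BzATP. Bars span the middle 95% of matched random lists, filled points lie outside them and open points inside; cholesterol synthesis lies at 0.14 and 0.31 against PBS.

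The comparison of A740003 with BzATP sets antagonist against agonist at the same dose and time. Mitotic genes were mostly higher and DNA replication and MHC class II genes mostly lower in the antagonist library than in the agonist library, and the lists of lipid synthesis genes had lower medians with members on both sides. G2/M genes had a median of 0.25, with 25 of 28 higher with A740003 and 0 lower, including BUB1 (0.46 [0.37 to 0.56]), CENPE, CCNB1 and BUB1B. DNA replication genes had a median of -0.17, with 22 of 28 lower and 1 higher, such as CDT1 (-0.75 [-0.87 to -0.62]), E2F1 (-0.47 [-0.55 to -0.39]), CDC45 and CCNE2. MHC class II genes had a median of -0.20, with 13 of 16 lower and 1 higher, among them HLA-DRB5 (-0.62 [-0.71 to -0.52]), HLA-DRB1, CD74 and HLA-DRA. Fatty acid synthesis genes had a median of -0.13, with 11 of 18 lower and 3 higher, led by the regulator SREBF1 (-0.78 [-0.92 to -0.65]) and FASN (-0.64 [-0.71 to -0.56]), then DGAT1 and FADS2. Cholesterol synthesis genes had a median of -0.10, with 13 of 24 lower and 3 higher, such as TM7SF2 (-0.51 [-0.62 to -0.40]), MVK, LSS and DHCR7. Mitochondrial mRNAs had a median of -0.42, with 12 of 13 lower, and nuclear-encoded respiratory chain genes one of -0.07, with 19 of 33 lower and 0 higher, including NDUFV1 and UQCRC1. Abundant noncoding RNAs had a median of 0.30, led by MT-RNR1 (1.35 [1.33 to 1.37]) and RN7SL2. Replication-dependent histones had a median of 0.50 over 8 measured genes of few reads, of which H2AC6 (33 reads against 15) and H2BC5 (49 against 27) were higher beyond counting error. Interferon-stimulated genes had a median of -0.21, with 8 of 17 lower and 2 higher, such as STAT2 (-0.59), IFI35, IFI6 and the regulator IRF1 (-0.63). NRF2 targets had a median of -0.11, with 11 of 17 lower and 2 higher, including GSR, FTH1 and NQO1 (-0.48). Autophagy and lysosome genes had a median of -0.15, with 13 of 31 lower and 3 higher, among them GAA, PSAP, CTSD (-0.43) and LAMP1. Glycolytic genes had a median of -0.09, with 12 of 20 lower and 2 higher, such as PFKL (-0.55), PKM, ALDOA and ALDOC. Ribosomal protein genes had a median of -0.01, with 33 of 77 lower and 13 higher, including RPL8, RPSA, RPS2 and RPL12, and turned to 0.03 under upper quartile scaling.

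By the rule of size, 84 genes were at least 2-fold higher and 80 at least 2-fold lower with A740003 than with BzATP. Of these, 38 and 56 were protein coding. The genes named next are ranked by the interval bound, and some are under 2-fold. Besides MT-RNR1, RN7SL2, RN7SL1, MT-ND6 and MT-RNR2, the highest were LINC00641 (1.22 [1.03 to 1.42]), DHRS2 (1.24 [0.95 to 1.53]), ATF5 (0.93 [0.84 to 1.01]), SNHG3 (0.70 [0.60 to 0.80]), FAM72D (0.95), UTP14C (0.93) and U2AF1L5 (0.67). The last 3 are uncertain for their copies: summed, the FAM72 family lay at 0.55 [0.47 to 0.62] and U2AF1 + U2AF1L5 at 0.03 [-0.03 to 0.09], and UTP14A, the parent gene of UTP14C, lay at 0.02 [-0.09 to 0.12]. SNHG3 turned to -0.66 in the FPKM values with a pseudocount of 0.1. The lowest were NGFR, with 295 reads against 791 (2.69-fold, -1.43 [-1.63 to -1.23]), the serotonin receptor HTR3A (-0.89 [-1.01 to -0.76]), MYO1G (-0.95 [-1.13 to -0.76]), RGS8 (-0.98 [-1.25 to -0.71]), GAA (-1.03 [-1.37 to -0.70]), the kinase FGR (-0.97 [-1.28 to -0.66]), PLEC, LUM, SIPA1, SREBF1, LIME1 and U2AF1, which is uncertain for the same reason. LUM, the proteoglycan lumican, had 73 reads with A740003, 152 with BzATP and 102 with PBS.

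The ratio of A740003 to BzATP was lower at higher GC content (Spearman -0.63 across 7034 genes), with decile medians from 0.13 to -0.27. With that trend removed, 9 of the 14 lists still stood apart, and glycolysis, ribosomal proteins, interferon-stimulated genes, NRF2 targets and autophagy and lysosome genes did not (medians of -0.09, -0.01, -0.21, -0.11 and -0.15 before removal and -0.03, -0.01, -0.07, -0.06 and -0.07 after it), while immediate early genes, ATF4 targets and ribosome biogenesis genes came to stand apart above their random lists (medians of 0.20, 0.10 and 0.10). Histones no longer stood apart with no filter (0.43), nor fatty acid synthesis (-0.11) and the respiratory chain (-0.04) in FPKM with a pseudocount of 0.1, and at a mean CPM of at least 5, 7 genes were called higher and 5 lower.

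Agonist and antagonist were also compared through their ratios to the same PBS library. Of the genes called in both comparisons, 49 were higher in both and 8 lower in both, against 1.43 and 0.311 for independent lists. Simulated unchanged libraries that share a control gave 5.70 in the same direction at an assumed coefficient of variation of 0.1 (54.1 at 0.2). On average 4.1 of these were higher in both and 1.6 lower in both (37.4 and 16.7 at 0.2). More higher than lower shared calls thus also arose without any change. At a mean CPM of at least 20 the covariance of both ratios lay near the simulated one at 0.1, as given above. At a mean CPM of at least 5, 5 genes were called in the same direction. Of all genes higher in both, LMO2 and WNK2 reached that mean CPM. NDRG1, also higher in both, did not, with 31, 30 and 13 reads with A740003, BzATP and PBS. Some shared calls are uncertain because of copies: SMIM11B was higher and SMIM11A lower in both. Their sum lay at 0.21 with A740003 and 0.15 with BzATP. P2RX5-TAX1BP3, higher in both, lay at 0.17 and 0.37 summed with P2RX5. In the same direction, 10 lists stood apart in both comparisons: NF-kB targets, cholesterol synthesis, FOXO targets, B-cell receptor signalling, cytokines and abundant noncoding RNAs were higher, and ribosome biogenesis, heat shock, ATF4 targets and glycolysis were lower. Simulated unchanged libraries that share a control gave at most 2 such lists in any of the 50 simulations at each coefficient of variation, and independent lists would give 2.53 higher and 1.17 lower; genes vary independently in those simulations, unlike genes of a pathway. With the GC and length trend removed, 11 lists stood apart in both in the same direction: 7 of the 10, without cytokines, abundant noncoding RNAs and glycolysis, and also apoptosis, ER chaperones, ribosomal proteins and germinal centre genes. Mitochondrial mRNAs stood apart in opposite directions. In opposite directions 5 genes were called, against 1.34 for independent lists and at most 1 in any simulation of unchanged libraries, and they were named after their values were seen: SMN2, ZNF625-ZNF20, GALNT4, POC1B-GALNT4 and ASDURF. Each shares sequence with another gene, and the sums SMN1 + SMN2, ZNF20 + ZNF625 + ZNF625-ZNF20, GALNT4 + POC1B-GALNT4 and ASDURF + ASNSD1 lay between -0.10 and 0.38 with A740003 and between -0.25 and 0.06 with BzATP. Across 11515 genes the ratios correlated at Pearson r = 0.54 with a covariance of 0.0612, against mean covariances of 0.0146, 0.0355 and 0.101 and a mean r of 0.51, 0.50 and 0.50 (highest 0.540, 0.526 and 0.522) in simulated unchanged libraries at the 3 assumed coefficients of variation. The observed r, 0.541, lay above each of these simulations. With the PBS reads split at random into 2 equal parts, 1 per comparison, r was 0.35 and 34 genes were called in the same direction. The single PBS library cannot be split into separate libraries, so part of any excess may come from that library.

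**Figure D4:**
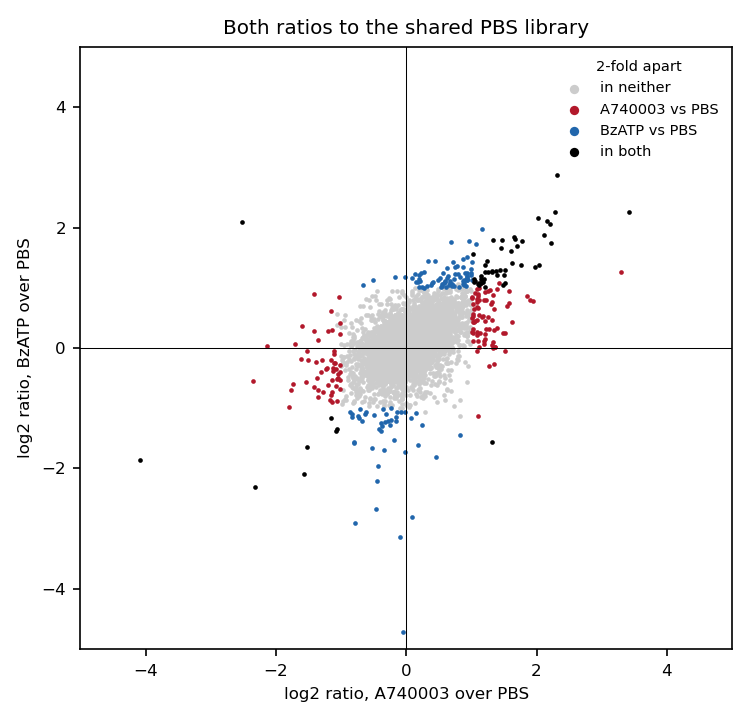
Log2 ratio of BzATP to PBS (vertical axis) against that of A740003 to PBS (horizontal axis) for the 11515 genes with reads in all 3 libraries; colours mark genes at least 2-fold apart in 1 comparison, in both or in neither. The cloud is tilted upward, with r = 0.54 for ratios that share the PBS library.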

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

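Removal of the GC and length trend and scaling without the A740003 library were chosen after seeing the data. Scaling by total counts, DESeq2 size factors or upper quartile, thinning, trend removal and leaving out the A740003 library kept the 2-fold counts within 1.5 times, though total counts moved the share of higher calls with A740003 against PBS from 66.5% to 79.0% and with BzATP against PBS from 69.9% to 78.5%, and trend removal that of A740003 against BzATP from 51.2% to 61.8%. No scaling moved the median ratio of all genes by over 0.1 (the farthest was 0.08, with total counts). Counts of higher and lower genes are given for A740003 to PBS, BzATP to PBS and A740003 to BzATP in turn. With no filter they were 401 and 179, 326 and 181, and 298 and 228, with 142 genes shared in direction against PBS; more genes were tested. At a mean CPM of at least 5 they were 18 and 8, 14 and 6, and 7 and 5, with 5 shared and 0 opposite; fewer genes were tested. At 1.5-fold they were 418 and 219, 442 and 173, and 251 and 341, and at 3-fold 25 and 14, 25 and 19, and 21 and 16. With FPKM and a pseudocount of 1 they were 60 and 24, 54 and 21, and 36 and 31, with 25 shared and 1 opposite, as the pseudocount shrinks ratios of low genes. With a pseudocount of 0.1, without a counting interval, 191 were higher with A740003 than with PBS and 86 were shared. Among protein-coding genes alone, 58 were higher with A740003 and 36 lower with BzATP than with PBS, and 38 higher with A740003 than with BzATP. With the PBS reads split into 2 equal parts, 34 were shared and 9 opposite. Ratios that changed sign were P2RY8 with BzATP to PBS (0.064 and 0.062 in FPKM), SNHG3 with A740003 to BzATP (-0.66 and -0.65 in FPKM), and CYC1, RPL8, RPS2 and ADORA2A with A740003 to BzATP (0.036, 0.051, 0.057 and 0.099 with the trend removed). The ribosomal protein median changed sign with BzATP to PBS under total counts (0.00011) and with A740003 to BzATP under upper quartile (0.031). The cause was not tested except where stated. Of the other medians of lists that stood apart in the main setting, 446 kept direction and stood apart, and 40 kept direction inside the random range. Lists that did not stand apart are not counted in these. Some of their medians changed sign with the trend removed, such as purinergic receptors with A740003 to BzATP (-0.09 to 0.16) and MHC class I with A740003 to PBS (-0.04 to 0.05). Of the ratios of named genes, 1197 stayed within their counting interval and 367 left it without a called ratio changing sign. P2RX7 was listed at 0.04 FPKM with PBS and at 0 in the other libraries. No paired analysis was possible because each treatment has 1 library, and DESeq2 tests, leaving out replicates and a replicate block had nothing to run on. Depth limits genes of few reads.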

Other observations

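The tests with the GC and length trend removed and the sums over gene copies were chosen after the results were seen, and the GC trend itself had been seen before its removal was tested.

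Of the lists that stood apart in no comparison before trend removal, germinal centre genes had medians of 0.02 with A740003 and 0.01 with BzATP against PBS, immediate early genes 0.09 and 0.11, p53 targets 0.09 and 0.04, plasma cell genes 0.10 and -0.00, PI3K and AKT components -0.03 and 0.00, immune checkpoint genes 0.04 and 0.10, calcium handling genes 0.02 and 0.01, and adhesion genes -0.05 and -0.02. With the trend removed, germinal centre genes stood apart above random lists with A740003 against PBS (percentile 99.9) and BzATP (percentile 97.9), and immediate early genes (percentile 99.5) and plasma cell genes (percentile 99.3) with A740003 against PBS. Some of their members are given here, chosen after their values were seen. IRAG2, a germinal centre gene, was at -0.67 [-0.70 to -0.64] with BzATP and at -0.16 [-0.19 to -0.13] with A740003. SERPINA9, another, was at 0.71 [0.57 to 0.85] and 0.37 [0.22 to 0.51]. TP53INP1, a p53 target, was at 0.76 [0.55 to 0.98] and 0.93 [0.72 to 1.14], and MYC, an immediate early gene with over 10000 reads in each library, at -0.28 [-0.32 to -0.24] and -0.02 [-0.06 to 0.02].

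Markers of T and NK cells, myeloid cells, erythroid cells and stroma were near 0 reads, except LCK (2372, 2705 and 2761 reads with A740003, BzATP and PBS) and DCN (742, 1242 and 1297), both chosen here after their values were seen. CD3D, CD2, S100A8, HBB and EPCAM had 0 reads in each library. AHRR, the repressor of the aryl hydrocarbon receptor, also chosen after its values were seen, had 77, 3 and 76 reads, a log2 ratio of BzATP to PBS of -4.72 [-7.03 to -3.12]. Summed with the readthrough gene PDCD6-AHRR it had 77, 69 and 76 reads, and the ratio was -0.20 [-0.69 to 0.29].

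MT-RNR1, MT-ND6, RN7SL1 and RN7SL2 were higher in the A740003 library, where most mitochondrial mRNAs were lower. The median log2 ratio of these 4 RNAs to PBS was 1.35. The trend with GC content, with decile medians from 0.12 to -0.23, is too small to give that. With the GC and length trend removed, 102% of the median was left. The size of the trend settled this outcome, so it does not test a bias particular to these RNAs. Less complete poly(A) selection in that library may account for the higher RNAs. The snRNA, snoRNA and scaRNA genes, which also lack poly(A) tails, summed to 182 reads. That was 1.63-fold [1.28 to 2.09] the 111 with BzATP and 1.68-fold [1.31 to 2.15] the 104 with PBS. Taken singly, these and other RNAs without such tails differed: with A740003, BzATP and PBS, snRNA had 73, 64 and 35 reads, snoRNA 105, 41 and 65, RN7SK 60, 54 and 34, RPPH1 12, 6 and 1, and RMRP 3, 11 and 13, and replication-dependent histones had a median log2 ratio of 0.50 to BzATP and 0.31 to PBS (in the latter within random lists), while the intervals above reach below the 1.5-fold set in advance. The use of poly(A) selection is not given in the sources used here, and an effect of A740003 or its solvent on mitochondrial RNA stays open and was not tested.

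The ratios of A740003 and BzATP to PBS correlated. The compounds have opposite actions on the P2X7 receptor, whose gene had 0, 0 and 1 reads with A740003, BzATP and PBS. A trend with GC content or length must be in both ratios to make them correlate. The ratio of BzATP to PBS had almost none (Spearman 0.04 with GC content and 0.006 with length), which argues against such a bias. That 103% of the covariance was left after the trend was removed follows from this and is no further test. A trend with mean CPM was in both ratios (Spearman -0.13 with A740003 and -0.27 with BzATP). It stayed at -0.21 and -0.25 with the GC and length trend removed. What it adds to the correlation was not tested. Independent differences between 3 libraries, of which PBS is shared, could give the pattern while the GC trend is left in. The covariance with PBS shared was then 1.18 times the mean of the covariances with A740003 or BzATP shared. Its bootstrap over genes gave 1.05 to 1.32, genes not being independent, below the 1.5 times set in advance. The GC trend lies in both ratios that share A740003 (Spearman -0.56 and -0.63), which raises that mean. With the trend removed, only the covariance with PBS shared was computed again, so the test cannot decide for ratios without the trend. Also, r, at 0.541 and at 0.588 with the trend removed, was above that of every simulation with equal variation in the 3 libraries (highest 0.540). A response common to both compounds stays open and was not tested, as does a PBS culture that differed from both for other reasons.

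The 191 genes at least 2-fold apart between A740003 and PBS followed the GC trend in part, with a median GC content of 47.6% for those higher and 56.9% for those lower, against 48.6% over all tested genes. That trend, with decile medians from 0.12 to -0.23, is too small by itself to give a 2-fold difference. Most calls were therefore bound to outlast its removal, and 82.7% did (111 of 127 higher and 47 of 64 lower). This does not test a GC bias that differs between single genes. For BzATP against PBS 94.1% were still called and for A740003 against BzATP 78.0%. An effect of the compound, one of its solvent and ordinary variation between cultures stay open, since no replicate measures the latter.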
